A study of Homo sapiens with 6 samples.

How the data were processed

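RNA was measured by sequencing in A549, an established human lung adenocarcinoma cell line, after transient transfection with an antisense oligonucleotide against MIR100HG or with a negative control oligonucleotide. Antisense oligonucleotides are short synthetic nucleic acids that pair with a target RNA, and MIR100HG is a long non-coding RNA gene that hosts microRNA genes. The sample titles gave 3 negative control and 3 knockdown libraries, each numbered 1 to 3. Libraries were made from total RNA with a Tn5 transposase kit, per the labels' protocols. The oligonucleotide is also named in those protocols; the deposited knockdown tables carry the abbreviation "sh" in their names, which the labels do not explain. No strand setting was given in the sources used here, so fragments of a gene and of an antisense or overlapping partner cannot be told apart. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

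The authors deposited 1 table per library with 62492 gene rows and 1 value per gene. The unit is not named in the files; the deposited values were taken to be FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, because they sum to between 794678 and 845845 per library and low values of single-exon genes fall in steps that scale with gene length. HISAT2, StringTie, DESeq2 and edgeR and the genome build hg19 are listed in the submitters' processing notes, without versions or settings, and how the authors made the FPKM values from the alignments is not given in the sources used here. Gene names came from a name table that held 58654 of the 62492 identifiers and gave a symbol for 40677 of them. The reference annotation used here is on another build than the authors' files, so no positions are given, and it served only for names, gene lengths and overlaps between genes.

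The step in these values, taken as 1 fragment, put the depth at between 17500000 and 23200000 fragments per library. Between 31.8% and 34.9% of low values of single-exon genes lay within 2% of a whole multiple of 0.5 steps, taken as a single read of a pair, where chance gives 15%. The steps were fitted to these same values, in a search from 0.03 to 0.08 in units of FPKM times gene length in kilobases, so the depths are implied, not counted. A gene at 1 FPKM would have between 17.5 and 23.2 fragments per kilobase. The files hold no counts, so counting intervals were not computed.

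The comparison of 3 knockdown with 3 negative control libraries used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend of the variance on mean expression and no block. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 7349 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the scale of log2(FPKM + 1), which understates the changes of genes with low values. A count model had been fixed as the main test for count tables and this limma fit as the test for FPKM tables, and the second applied. The test, the 35 gene lists, the rule for naming genes and the alternatives not listed below as added were chosen before the data were examined.

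Gene lists with at least 5 tested members were tested with camera in limma, with a preset correlation between genes of 0.01 and with an estimated correlation beside it. With an estimated correlation camera uses the 4 residual degrees of freedom of the fit. Few lists could pass that way, so a failure there is weak evidence of no change. Camera compares the members with all other genes, so a list can be lower by this test with a median fold change above 0. Of 970 listed genes, 964 were found in the files. Members are reported over all genes tested and adjusted over the list alone. The rule named MIR100HG, ACSL3 and the members of the MIR100HG locus. It also took the 10 largest changes per direction among genes past the threshold with a mean of at least 5 FPKM, a symbol and groups that did not overlap, which gave 0 genes. From each described list it took up to 4 members with the smallest adjusted p, and members needed to show no call. Of the 54 tested genes named, 37 overlap another annotated gene. XAGE1A and genes of the ferritin and ribosomal protein families and of the mitochondrial genome have near-identical copies in the nuclear genome. The values of all these genes are therefore uncertain. Single values were compared with exact two-sided permutation tests, which cannot go below p = 0.1 for 3 against 3 libraries.

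The fit was tested on simulated data for this comparison with 7349 genes, of which 200 were changed. It recovered 22.4% of genes changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and 97% of those changed by 2, with 9 false calls. The simulated noise was independent between genes and held no shift of a whole library. Recovery also depends on how many genes change, so it may be lower in the real comparison. Alternatives covered another pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, a minimum absolute log2 fold change of 1, an estimated correlation for the gene lists, and leaving out each library in turn. Array weights, cyclic loess, centring on the library median, leaving out 2 libraries together, and an estimated correlation combined with no filter or with centring were added after seeing the data.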

Results

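The series measured gene expression in A549 cells transfected, per the labels, with an antisense oligonucleotide against MIR100HG, with 3 libraries, and in cells transfected with a negative control oligonucleotide, with 3 libraries. Its stated purpose was to find genes downstream of MIR100HG. Its title names ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, and ACSL3, which activates long-chain fatty acids to acyl-CoA. The implied depth was 17500000, 19000000 and 20600000 fragments in negative control replicates 1 to 3 and 19700000, 21500000 and 23200000 in knockdown replicates 1 to 3. Between 7227 and 7606 genes per library had at least 1 FPKM. Pearson's r across genes, which are not independent replicates, was between 0.986 and 0.988 within groups and between 0.983 and 0.988 across groups.

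MIR100HG (ENSG00000255248.9_8), the target of the knockdown, had 1.80 ± 0.18 FPKM (SD, n = 3) in the negative control and 1.08 ± 0.41 FPKM (SD, n = 3) in the knockdown libraries, or 59.8% of the control level. The control libraries held 2.01, 1.69 and 1.71 FPKM and the knockdown libraries 0.72, 1.53 and 0.98 FPKM, so that every knockdown value lay below every control value. Its log2 fold change was −0.45 ± 0.16 (SE), with an adjusted p of 0.421 in limma over all genes tested, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The unadjusted p in limma was 0.0246. MIR100HG was the 1 member of its locus list with enough signal to be tested, which left nothing to adjust over the list. The microRNA genes hosted in the locus had little or no signal: MIR100 and MIR125B1 were listed at 0 in all 6 libraries and MIRLET7A2 in 3 of them. None of the 6 was a small RNA library, so these values do not tell whether the microRNAs were present or changed. BLID, a small gene within the locus, had 0.12, 0.000004 and 0.084 FPKM in the control libraries and 0.087, 0.12 and 0 FPKM in the knockdown libraries. At about 1 to 2 FPKM the reduction of MIR100HG did not pass after adjustment over the 7349 genes tested. Taken alone, as a target named beforehand, it exceeded the spread between these replicates, which may be technical (limma, unadjusted p = 0.0246).

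ACSL3 (ENSG00000123983.14_4) had 1.68 ± 0.28 FPKM (SD, n = 3) in the negative control and 2.47 ± 0.49 FPKM (SD, n = 3) in the knockdown libraries, 1.47 times the control mean. The control libraries held 1.84, 1.85 and 1.35 FPKM and the knockdown libraries 2.50, 2.95 and 1.96 FPKM, with no overlap between groups. The log2 fold change was 0.37 ± 0.15 (SE), with an adjusted p of 0.438 in limma. The exact permutation test again gave p = 0.1. Of the other acyl-CoA synthetases, ACSS2, which makes acetyl-CoA from acetate, had 1.74 ± 0.46 and 2.44 ± 0.21 FPKM, ACSM3 had 4.39 ± 0.58 and 5.48 ± 1.06 FPKM, and ACSF2 had 2.43 ± 0.28 and 3.02 ± 0.68 FPKM in control and knockdown libraries. All 6 tested members of this list had positive log2 fold changes, above the median of all genes, and none passed the test, over all genes or adjusted over the list alone. The list did not pass as a group (camera, adjusted p = 0.221, or 0.649 with an estimated correlation).

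**Figure D1:**
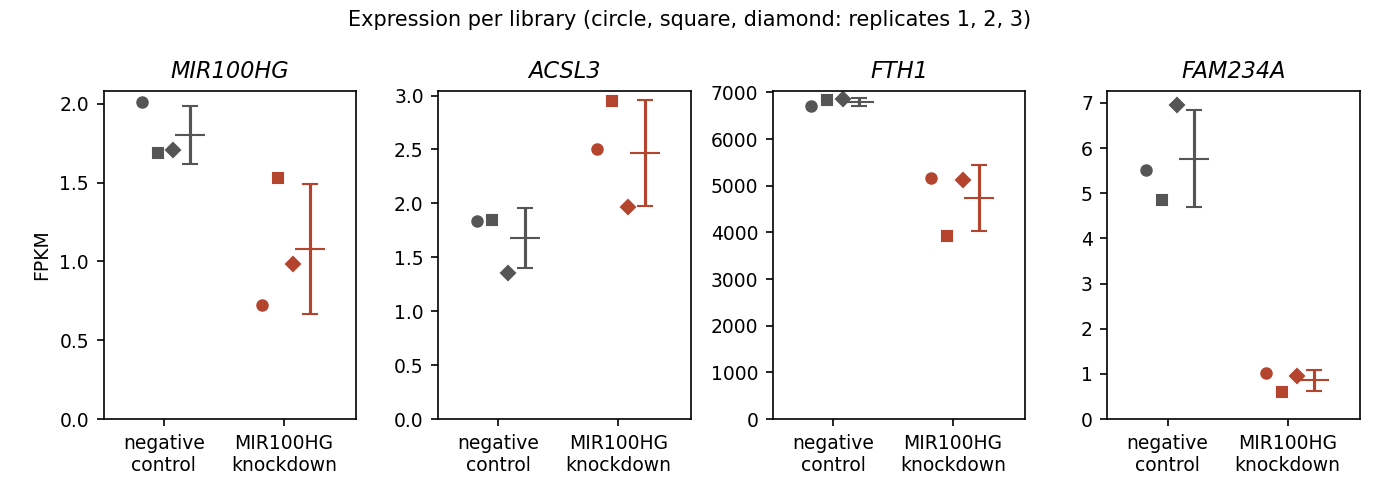
FPKM per library for MIR100HG, ACSL3, FTH1 and FAM234A, each panel with its own axis from 0. Symbols are libraries and horizontal marks with bars are the group mean ± SD (n = 3); MIR100HG lies at 1.80 and 1.08 FPKM, ACSL3 at 1.68 and 2.47, FTH1 at 6796 and 4738, and FAM234A at 5.77 and 0.86 in control and knockdown libraries.

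Across all 7349 genes tested, 0 genes rose and 1 gene fell after knockdown (limma, adjusted p under 0.05). The gene that fell was FAM234A, at 5.51, 4.84 and 6.95 FPKM in the control libraries and 1.01, 0.60 and 0.96 FPKM in the knockdown libraries, a log2 fold change of −1.86 ± 0.16 (SE) with an adjusted p of 0.0146. FAM234A falls outside the rule for naming genes by size and was singled out after its values were seen. Its call ended without negative control replicate 1 (adjusted p = 0.0532), without negative control replicate 3 (0.0722), without knockdown replicate 2 (0.0645), without both negative control replicate 1 and knockdown replicate 2 (0.127), and without the filter on low values (0.614). In these fits its log2 fold change lay between −1.88 and −1.74, with an SE between 0.15 and 0.19. The genes overlapping it, RGS11 and ARHGDIG, had means of 0.11 and 0 FPKM in the control and 0.082 and 0.041 FPKM in the knockdown libraries. At an unadjusted p under 0.05 there were 830 genes, of which 702 were higher and 128 lower, where chance gives 367. This split depended on scaling: it was 258 higher and 296 lower with quantile normalization, 253 and 304 with cyclic loess, and 263 and 322 with centring on the library median. Every knockdown library lay above every control library for 1211 genes (16.5%) and below for 213 genes (2.90%), where chance gives 5% each way. These counts were made on the values without such scaling only, so a shift of whole libraries enters them too. The median log2 fold change of all genes was 0.093, and knockdown replicate 2, which stood apart on the first principal component, had a median of 0.16 against the control mean, compared with 0.072 and 0.054 in replicates 1 and 3.

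Among genes that restrain ferroptosis, FTH1 was lower in the knockdown libraries, at 6796 ± 85.4 FPKM (SD, n = 3) in the control and 4738 ± 705 FPKM (SD, n = 3) in the knockdown libraries. FTH1 encodes the heavy chain of ferritin, which stores iron, and its gene overlaps BEST1 and has near-identical pseudogenes, so its values are uncertain. Its log2 fold change was −0.53 ± 0.10 (SE), with an adjusted p of 0.410 over all genes tested in limma and of 0.0245 adjusted over the list alone. FTH1 therefore fell only by the second measure, which does not adjust for the number of lists examined. FTL, the light chain of ferritin, had 55454 ± 760 and 57157 ± 2781 FPKM, a positive log2 fold change of 0.04 that was 0 with quantile normalization and −0.05 with centring on the library median. GPX4, which reduces lipid hydroperoxides, had 37.0 ± 3.20 and 34.8 ± 1.93 FPKM. SLC7A11, the cystine transporter subunit, had 2.82 ± 0.14 and 2.81 ± 0.39 FPKM, a log2 fold change of −0.01. NQO1, a quinone reductase, had 1411 ± 49.0 and 1179 ± 159 FPKM, and MBOAT1, a phospholipid acyltransferase, had 3.17 ± 0.08 and 3.97 ± 0.33 FPKM. ACSL3, described above, is also on this list and had a positive log2 fold change. Of the 33 tested members of this list, 19 had positive log2 fold changes, and 23 lay below the median of all genes. Over all genes 0 passed and 1 adjusted over the list alone, and the group did not pass (camera, adjusted p = 0.160, or 0.563 with an estimated correlation). The group passed in the lower direction with centring on the library median (adjusted p = 0.0427, or 0.649 with an estimated correlation).

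Genes that promote ferroptosis did not pass as a group either, with 19 of 26 tested members at positive log2 fold changes but 15 of the 26 below the median of all genes (camera, adjusted p = 0.788, or 0.842 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, had 2.49 ± 0.31 FPKM in the control and 1.71 ± 0.22 FPKM in the knockdown libraries. ATP5MC3, a subunit of ATP synthase, had 24.4 ± 7.71 and 40.1 ± 10.2 FPKM, BECN1, an autophagy gene, had 55.5 ± 5.44 and 69.8 ± 10.5 FPKM, and SAT1, a polyamine acetyltransferase, had 467 ± 31.1 and 522 ± 32.3 FPKM. None of the 26 passed the test, over all genes or adjusted over the list alone.

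Of the 29 lists that could be tested, 3 were lower than the other genes by camera with the preset correlation, and 0 passed with an estimated correlation. The second setting is stricter for more than the correlation, as it rests on 4 residual degrees of freedom. For interferon-stimulated genes the unadjusted camera p rose from 0.0797 to 0.143 under it, although their estimated correlation, −0.085, was below the preset 0.01. Mitochondrially encoded genes, which specify respiratory chain subunits and ribosomal RNAs, had negative log2 fold changes in 13 of 15 tested members, with a median of −0.15 against 0.09 for all genes (adjusted p = 4.96e-12, or adjusted p = 0.563 with an estimated correlation). The estimated correlation of this list was 0.32, against 0.093 for NRF2 targets and 0.085 for ribosomal protein genes. All 3 exceed the preset 0.01, so adjusted p-values with the preset correlation may be too small for these lists. MT-RNR1 had 1566 ± 33.1 FPKM in the control and 1318 ± 101 FPKM in the knockdown libraries, MT-ND2 had 746 ± 34.0 and 653 ± 16.9, MT-CO3 had 25548 ± 586 and 21032 ± 2712, and MT-ND5 had 1832 ± 3.74 and 1468 ± 253. For each of these 4 genes every knockdown library lay below every control library, and 0 of the 15 passed the test over all genes or adjusted over the list alone. The list median minus that of all genes was −0.25, with quartiles of −0.35 and −0.21, and −0.13 with cyclic loess (adjusted p = 3.99e-05). With quantile normalization it was −0.07, with quartiles of −0.20 and 0.03, and this smaller shift did not pass (adjusted p = 0.120). Relative to the control mean and to all genes, the list medians were −0.22, −0.42 and −0.14 in knockdown replicates 1, 2 and 3. The control libraries had −0.02, 0.03 and −0.01.

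NRF2 targets, genes of the antioxidant response, had a median log2 fold change of −0.05, with 18 of 30 tested members negative (camera, adjusted p = 2.73e-05, or adjusted p = 0.563 with an estimated correlation). FTH1 was the 1 member that fell adjusted over the list alone (adjusted p = 0.0223). TRIM16L had 126 ± 7.62 FPKM in the control and 100.2 ± 11.9 FPKM in the knockdown libraries. SRXN1, which reduces oxidised peroxiredoxins, was listed at 0 in knockdown replicates 1 and 2 and had 4.39 FPKM in knockdown replicate 3, against 4.45, 3.42 and 3.78 FPKM in the control libraries. The list median minus that of all genes was −0.14, and −0.07 without knockdown replicate 2 (adjusted p = 0.0273). It was −0.08 with quantile normalization (adjusted p = 5.90e-04) and −0.09 with cyclic loess (2.78e-04). Without the filter on low values it was −0.04 and the list did not pass (adjusted p = 0.0686). In knockdown replicates 1, 2 and 3 the list medians, relative to the control mean and to all genes, were −0.11, −0.25 and −0.03, against −0.02, 0.03 and −0.01 in the control libraries.

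Ribosomal protein genes had a median log2 fold change of −0.02 and a mean of 0.02, with 41 of 69 tested members negative (camera, adjusted p = 0.00532, or adjusted p = 0.649 with an estimated correlation). The members with the smallest adjusted p went the other way: RPL23 had 31.1 ± 2.46 and 53.2 ± 12.8 FPKM in control and knockdown libraries, RPS10 had 27.7 ± 1.80 and 35.3 ± 1.21 FPKM, RPS2 had 82.0 ± 1.28 and 104.6 ± 12.8 FPKM, and RPL37 had 7.14 ± 5.68 and 16.8 ± 1.12 FPKM. The list did not pass without knockdown replicate 2 (adjusted p = 0.715), without negative control replicate 2 (0.178), with array weights (0.0981), without both negative control replicate 1 and knockdown replicate 2 (0.412) or without the filter on low values (0.525). The list median minus that of all genes, −0.11, was −0.05 without knockdown replicate 2, −0.06 without both libraries and −0.03 without the filter. In knockdown replicates 1, 2 and 3 the list medians, relative to the control mean and to all genes, were −0.05, −0.19 and −0.02, against −0.01, 0.04 and −0.01 in the control libraries.

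**Figure D2:**
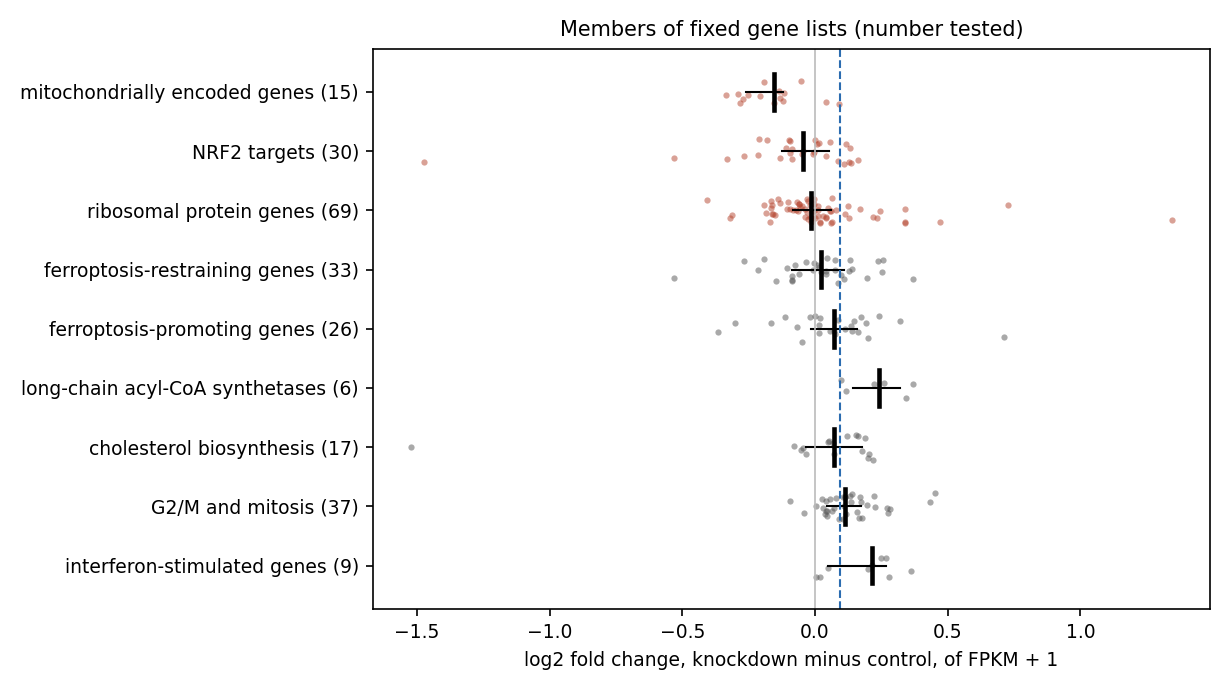
Log2 fold change of FPKM + 1 (knockdown minus control) for the tested members of 9 gene lists, with the number tested in brackets. Points are genes, red for the 3 lists that passed camera with the preset correlation, thick ticks are medians, thin lines span the quartiles and the dashed line is the median of all genes at 0.09; the mitochondrially encoded genes have their median at −0.15.

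None of the 3 other lipid lists passed. In cholesterol biosynthesis, FDPS had 146 ± 4.75 FPKM in the control and 168 ± 12.9 FPKM in the knockdown libraries, and ACAT2 had 73.4 ± 3.83 and 85.6 ± 6.58 FPKM. CYP51A1, the lanosterol demethylase, had 4.40 FPKM in knockdown replicate 1 but 0.15 and 0.25 FPKM in replicates 2 and 3, against a control mean of 4.69 ± 0.35 FPKM. Of 17 tested members 12 were positive and 8 above the median of all genes (camera, adjusted p = 0.943). In fatty acid synthesis and desaturation, ELOVL1 had 81.7 ± 5.35 and 102.7 ± 17.0 FPKM (list adjusted p = 0.772). In fatty acid oxidation and lipid storage, ETFB had 333 ± 12.5 and 394 ± 19.6 FPKM, HADHA had 23.9 ± 0.94 and 28.7 ± 1.21 FPKM, and ACAA2 had 14.4 ± 3.24 and 19.2 ± 0.55 FPKM (list adjusted p = 0.739). No member of these 3 lists passed the test over all genes or adjusted over the list alone.

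Cell cycle genes, like most genes, had mostly positive fold changes, and did not pass as groups. Of 37 tested G2/M and mitosis genes 35 were positive and 22 above the median of all genes (camera, adjusted p = 0.193). Of 30 G1/S and DNA replication genes 25 were positive and 19 above it (0.221). With an estimated correlation the adjusted p was 0.649 for both. Both lists passed in the higher direction without the filter on low values (adjusted p = 2.36e-04 and 0.00164), but not there with an estimated correlation (0.645 and 0.471). Without the filter the lists were set against 28375 genes, with a median log2 fold change of 0.012, against 0.093 with it. A list that shared the general rise stands higher there, so passing there does not show a change particular to the list. NUF2, a kinetochore protein, had 4.93 ± 0.84 FPKM in the control and 7.07 ± 0.28 FPKM in the knockdown libraries, TTK, a mitotic checkpoint kinase, had 1.29 ± 0.20 and 2.09 ± 0.29, and NUSAP1 had 46.6 ± 2.75 and 56.8 ± 7.09. GINS2, part of the replicative helicase, had 18.5 ± 0.40 and 22.0 ± 1.02 FPKM, and E2F1 had 1.63 ± 0.09 and 2.31 ± 0.25 FPKM. Of the nuclear-encoded oxidative phosphorylation genes, 28 of 36 had positive fold changes and 19 lay above the median of all genes (camera, adjusted p = 0.221, or 0.649 with an estimated correlation), with COX6A1 at 1129 ± 47.9 and 1393 ± 217 FPKM and NDUFA2 at 77.2 ± 4.08 and 89.6 ± 2.61 FPKM. The difference from the mitochondrially encoded list was not tested. This list also passed in the higher direction without the filter on low values (adjusted p = 0.00164, or 0.471 with an estimated correlation).

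Stress and signalling lists did not pass. All 9 tested interferon-stimulated genes had positive fold changes, 6 of them above the median of all genes (camera, adjusted p = 0.221), with OAS1 at 23.2 ± 2.31 and 28.0 ± 0.56 FPKM and IFI35 at 45.3 ± 3.33 and 54.0 ± 4.13 FPKM in control and knockdown libraries. Among p53 targets (adjusted p = 0.213), AEN had 2.07 ± 0.08 and 2.95 ± 0.15 FPKM and GDF15 had 9.96 ± 1.57 and 7.99 ± 1.82 FPKM. XBP1 and HERPUD1, of the unfolded protein response, had 10.8 ± 0.73 and 13.9 ± 1.20 FPKM and 81.9 ± 3.39 and 97.6 ± 7.21 FPKM (list adjusted p = 0.385), and HSP90AB1, of the heat shock response, had 159 ± 8.80 and 186 ± 10.4 FPKM (0.612). Reported targets of the microRNAs hosted by MIR100HG did not pass as groups: for miR-100 and miR-125b the adjusted p was 0.849, with PPP1CA at 142 ± 6.44 and 168 ± 6.40 FPKM, and for let-7 it was 0.968, with NRAS at 0.83 ± 0.02 and 1.25 ± 0.10 FPKM. By camera the adjusted p was 0.206 for long non-coding RNAs listed as nuclear-retained and 0.221 for hypoxia and glycolysis. It was 0.244 for immediate early genes and for epithelial genes, and 0.374 for the amino acid stress response and for the TGF-beta response. Mesenchymal genes had 0.569, Wnt targets 0.768, NF-kB and inflammatory genes 0.772, lysosome and autophagy 0.788, and histones 0.943.

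Few markers of other cell types reached the level needed for a test. No fibroblast or endothelial marker reached a mean of 1 FPKM, that is 0 of 12 and 0 of 11 in the files. Of 16 immune markers 2 did, CD68 at 2.97 ± 0.23 and 2.35 ± 0.80 FPKM and CD14 at 4.35 ± 0.04 and 4.75 ± 0.80 FPKM in control and knockdown libraries. Of 15 genes listed as markers of cervical and kidney culture lines 1 did, XAGE1A, a cancer-testis gene. It had 16.1, 5.73 and 9.78 FPKM in the control libraries, was listed at 0 in knockdown replicate 1 and had 9.87 and 17.9 FPKM in knockdown replicates 2 and 3. XAGE1A is not particular to these lines and has a near-identical copy, so its values are uncertain and do not show such cells. Of 26 alveolar and lung lineage genes 4 were tested. No marker passed the test.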

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

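Array weights, cyclic loess, centring on the library median, leaving out both negative control replicate 1 and knockdown replicate 2, and combining an estimated correlation with no filter or centring were chosen after seeing the data. MIR100HG stayed lower and ACSL3 higher, neither past the threshold, under every alternative run, with log2 fold changes between −0.75 and −0.32 for MIR100HG and between 0.27 and 0.53 for ACSL3. The count of genes higher, 0 of 7349, ranged from 0 to 4 when 1 library was left out and was 1 without both doubted libraries. The count of genes lower, 1, ranged from 0 to 3 when 1 library was left out and was 0 without the filter on low values, where 28375 genes were tested. With the replicate number as a block it was 0 lower and 0 higher, with 633 genes at an unadjusted p under 0.05. Deviations of same-numbered libraries correlated at −0.06, −0.09 and 0.00, and 1 of 6 libraries correlated best with its own number. The values thus gave no sign that the numbers pair the samples, but a weak pairing cannot be excluded. The count of gene lists past the threshold, 3, was 0 with an estimated correlation, alone, without the filter on low values and with centring on the library median. With the preset correlation it ranged from 2 to 3 when 1 library was left out, was 4 with centring and 4 without the filter (1 lower, 3 higher, with NRF2 targets and ribosomal protein genes lost), and 2 with quantile normalization, array weights or without both doubted libraries. Without the filter the median log2 fold change of all genes was 0.012 instead of 0.093. The lists gained and lost there may therefore reflect the other genes compared. The sign turned for FTL with centring on the library median (−0.0511), for CD14 with quantile normalization (−0.0072) and cyclic loess (−0.0092), and on leaving out 1 library for SLC7A11 (between −0.0887 and 0.0516), CD14 (between −0.0179 and 0.15), XAGE1A (between −1.70 and 0.41) and MALAT1 (between −1.73 and 0.038); no call was involved. Of the other 52 named genes' values under the alternatives, 704 kept their sign and side of the threshold and 1 was 0 (FTL with quantile normalization). A call was lost in 6, each of FAM234A (with the replicate number as a block, adjusted p = 0.0567 in limma), and gained in 5. The gains were RPL37 (higher) without negative control replicate 1 and SRXN1 (lower) without knockdown replicate 3. Without knockdown replicate 1 they were CYP51A1 (lower), RPL23 and BEST1 (both higher). The cause of these changes was not tested. DESeq2 size factors, the DESeq2 Wald test, limma-voom and a filter on CPM need counts and were not run. TPM, which FPKM gives by scaling each library to the same sum, was not run either. Genes near 1 FPKM rest on about 20 fragments per kilobase, which limits MIR100HG and ACSL3.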

Other observations

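The tests in this part were chosen after the results were seen, except the mitochondrial share, the gene lists over other splits, the estimated correlation and leaving out each library in turn. A few genes had values in single libraries far from those of the others. BEST1, a chloride channel gene that overlaps FTH1, had 0.67, 0.41 and 0.46 FPKM in the control libraries and 0.29, 107 and 267 FPKM in knockdown replicates 1, 2 and 3. SRXN1 was listed at 0 in knockdown replicates 1 and 2, CYP51A1 lay at 0.15 and 0.25 FPKM in knockdown replicates 2 and 3, and XAGE1A was listed at 0 in knockdown replicate 1. Of the 100 genes with the largest absolute log2 fold changes, 84% overlap another annotated gene, against 68.9% of all genes tested. Knockdown replicate 2, with the smallest reduction of MIR100HG (1.53 FPKM), had the highest ACSL3 value (2.95 FPKM). The mitochondrial share of fragments was 25.4% ± 0.25 in the control and 24.2% ± 0.82 in the knockdown libraries (exact permutation p = 0.1), which alone would raise other genes by 0.0225 on the log2 scale, against the 0.09 observed.

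FTH1 was lower in all 3 knockdown libraries. Had its fragments moved to the 25 FTH1 pseudogenes or to BEST1, these would have gained most of the lost fragments, taken as FPKM times length. The pseudogenes together had 87.5 ± 1.57 FPKM in the control and 65.0 ± 11.6 FPKM in the knockdown libraries. With each gene held at the same annotated length in both groups, they and BEST1 gained at most 41.2% in knockdown replicates 1 and 2. A change between FTH1 transcripts of different length would alter this bound and was not tested. In knockdown replicate 3 the lengths leave a range from 14.4% to 181.6%, so a move to BEST1 cannot be told apart from a loss there. A drop of this size shared by abundant genes is argued against by the 67 other genes at 1000 FPKM or more. Their median log2 fold change was −0.0124, where the interval of FTH1 ran from −0.77 to −0.30. They did lie below the median of all genes, 0.093. The 17 non-mitochondrial genes at 4000 FPKM or more, FTH1 among them, had a median of −0.055. A smaller drop shared by abundant genes may therefore be part of the FTH1 change. Knockdown replicate 2 alone is argued against by the log2 fold change without it, −0.40 ± 0.04 (SE). An effect of the knockdown on FTH1 stays open as a hypothesis, found and tested on the same libraries, and other technical causes were not tested.

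Of the lists that passed, 7 of 15 mitochondrially encoded genes, 26 of 30 NRF2 targets and 69 of 69 ribosomal protein genes had 50 neighbours in abundance with a median FPKM within 1.5 times their own. The medians of these members lay at percentiles 0.05, 0.01 and 0 of 10000 random lists of such neighbours. The random lists were drawn gene by gene and hold no correlation between members, so these percentiles may be too extreme. The 3 lists were also picked because they were lower in these libraries. Within these limits the percentiles argue against a trend with abundance for these members. For the 8 other mitochondrially encoded genes, with 4 other genes as abundant as the lowest of them, such a trend cannot be told apart from a change of their own. Without knockdown replicate 2 the medians minus that of all genes went from −0.25 to −0.18 for the mitochondrially encoded genes, from −0.14 to −0.0674 for the NRF2 targets and from −0.11 to −0.0502 for the ribosomal protein genes (adjusted p = 1.57e-09, 0.0273 and 0.715). In knockdown replicates 1 and 3 the mitochondrially encoded genes lay below the control libraries by more than 2 SD of these (−0.22 and −0.14), which argues against that library alone, but the NRF2 targets did so in replicate 1 only, which leaves it open, and it may account for the call of the ribosomal protein genes, which also ended without negative control replicate 2 (adjusted p = 0.178). None of the 3 lists passed with an estimated correlation (adjusted p = 0.563, 0.563 and 0.649), and an effect of the knockdown on these genes stays open.

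MALAT1, a nuclear long non-coding RNA, had 53060 FPKM in negative control replicate 1, against 4552 and 8485 FPKM in the other control libraries and between 5396 and 8571 FPKM in the knockdown libraries. If this were full-length RNA of 8708 nucleotides it would take 46.2% of that library's fragments and lower the other genes by 0.81 on the log2 scale (predicted difference −0.81), but their median difference from control replicates 2 and 3 was 0.023. The 7 other tested RNAs of the list named nuclear-retained differed by a median of 0.0742 and by at most 0.27. This argues against a gain shared by the listed RNAs. Some RNAs of that list, such as NORAD and GAS5, are not strictly nuclear, so nuclear RNA as a whole was not tested. An assignment of fragments to a short MALAT1 transcript, of which the shortest annotated has 132 nucleotides and would leave the others nearly in place (predicted difference −0.0089), cannot be told apart from other estimation errors without values per transcript. No other explanation was tested, and the high library shares its group with low ones.

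With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 1 gene past the threshold and the highest of the others 2, and 5 of the 10 splits gave at least as many. It gave 3 gene lists, the highest of the others 4, and 4 of the 10 gave at least as many. It gave 830 genes at an unadjusted p under 0.05, the highest of the others 483, and 1 of the 10, the real one, gave as many.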
